A study of Mus musculus with 7 samples.

How the data were processed

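The study used mouse J1 embryonic stem cells, a line derived from the inner cell mass of a male embryo, that carry the biotin ligase BirA. BirA attaches biotin to a tagged protein, so that streptavidin beads can pull the protein down together with its bound DNA (bioChIP). Arid3a, an AT-rich DNA-binding protein, was captured in this way from cells with high and with moderate overexpression. HDAC1, a histone deacetylase and a subunit of several co-repressor complexes, was captured with an antibody from control cells and from Arid3a-overexpressing cells. Per the labels' protocols, chromatin was crosslinked with formaldehyde and sonicated before the pull-down, and libraries were made from the recovered DNA and sequenced.

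The series holds 7 samples in 7 groups of 1 library each. The 4 ChIP samples have 1 peak list each. The 3 mock samples (BirA cells, and a mock pull-down from each of the 2 HDAC1 cell types) have no file of their own and enter no comparison. The group of each sample was taken from its treatment label or its title. The library called "low" in its title is labelled as moderate overexpression in its treatment field and is called moderate here. The labels do not say whether the HDAC1 libraries from overexpressing cells came from the high or the moderate clone.

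The authors deposited peak lists of 5 columns without a header: chromosome, start, end, a peak name that begins with MACS, and a score. The submitters' processing notes name CASAVA 1.7, BWA 0.5.9-r16, MACS without a version, and the mouse genome build mm9. The control library, the significance threshold and any filter applied after calling are not given in the sources used here. Each of the 4 samples has a list of its own, so the lists were compared as single libraries. The score is the authors' own value for each deposited peak, and its scale is not given in the sources used here. The lowest score was 50.01 in 3 of the 4 lists and 92.5 in the moderate Arid3a list, which may therefore have been called or filtered in another way than the others. A score of exactly 3100 was carried by 24 peaks of the high-overexpression and 513 peaks of the moderate Arid3a list, so ranks among those peaks carry no information. Scores were used to rank peaks, and to give medians per chromosome, within their own list. The lowest score and the number of peaks at 3100 describe how the lists differ. Scores of peaks from different lists are each on the scale of their own list, and no difference between them was read as a change. The files give no read counts, so the sequencing depth of each library is unknown.

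Positions are given in mm9, counted from 1. Peaks of 2 lists were called overlapping when they shared at least 1 bp. Each share of peaks is printed with its exact Clopper-Pearson 95% interval, which covers the counting of peaks only and says nothing about variation between cultures. With 1 library per group there is no replicate error and no test between groups, so no p-value is given. To show what chance placement gives, each list was shifted 1000 times around its chromosomes by a random offset per chromosome, within the span that the 4 lists cover, and the overlap was counted again. Within a list, peaks were split into 10 equal parts by score (deciles; decile 10 is the highest). The odds that a control HDAC1 peak was listed again in overexpressing cells were compared between peaks with and without an Arid3a peak by a Mantel-Haenszel odds ratio over the deciles of the control HDAC1 score, with the Robins-Breslow-Greenland interval. The same odds ratios were computed in the other direction, for peaks from overexpressing cells found in the control list over deciles of their own score. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

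The overlap code was tested against bedtools 2.31.1 for 12 ordered pairs of lists, and 0 pairs differed. In a simulated list of 2000 peaks, 40% were planted on high-overexpression Arid3a peaks. The overlap above the mean of the shifts, divided by the largest excess possible over that mean, gave 40.3%. The shares reported below are not rescaled in this way. In simulated strata with a true odds ratio of 2, the stratified estimate was 2.04.

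The design, the gene lists and the alternatives were fixed before the data were examined. The rule for named regions took the 10 highest-scoring peaks of each list and the 10 highest-scoring HDAC1 peaks on an Arid3a peak that were listed in only the control or only the overexpressing cells. The alternatives were another overlap rule (midpoints within 250 bp, at least 50% of the shorter peak, or peaks widened by 500 bp on each side), the top 50% of each list by score, equal list sizes, autosomes only, and removal of regions listed in all 4 (overlapping peaks of the 4 lists joined into 1 region). Leaving out peaks narrower than 250 bp, leaving out chromosome 1, the stratification of the odds ratio by score and its other forms and direction, and the odds ratio between the highest and the lowest of 4 equal groups by Arid3a score were added after the data were seen. For equal list sizes, the longer list was reduced to its highest-scoring peaks, as many as the shorter list holds. Comparisons that need gene positions or sequence (promoter shares, the fixed gene lists, base composition) were not made, because the only annotation used here is of another genome build than the peaks and coordinates were not converted.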

Results

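Binding of Arid3a was profiled in mouse J1 embryonic stem cells that overexpressed it at a high or a moderate level, and HDAC1 was profiled in control and in Arid3a-overexpressing cells. The design raises 3 questions: which Arid3a regions are listed at both levels, which HDAC1 regions are listed with and without overexpression, and where the peaks of HDAC1 and Arid3a coincide. The peak lists held 60047 regions for Arid3a at high overexpression, 1013 for Arid3a at moderate overexpression, 3833 for HDAC1 in control cells and 1348 for HDAC1 in overexpressing cells. They covered 47.8, 0.381, 2.77 and 1.56 Mb of the genome, respectively. Each group is 1 library of unknown depth, so differences between lists carry no replicate error, and a region missing from a list is not shown to be unbound.

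Far more Arid3a regions were listed for the cells with high overexpression. Their list held 59.3 times as many peaks as the list from moderate overexpression and covered 125 times as much sequence. The lowest score was 92.5 in the moderate list and 50.01 in the other 3, and 513 moderate peaks had a score of exactly 3100, so the moderate list may have been called or filtered in another way, which would alter both ratios and the widths. Of the 1013 moderate peaks, 352 (34.7%; 95% interval 31.8 to 37.8%) overlapped a high-overexpression peak, while 661 did not. Random placement of the moderate peaks gave 2.83% on average and at most 4.64% in 1000 shifts. In the other direction, 351 of 60047 high-overexpression peaks (0.585%) overlapped a moderate peak, against 0.0487% on average by shifting. Of the moderate peaks, 7.11% overlapped the 1013 highest-scoring peaks of the high-overexpression list and 22.7% were shared by midpoints within 250 bp.

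The shared regions lay mostly among the highest-scoring Arid3a regions of the high-overexpression list. In the highest decile of score, 161 of 6004 peaks (2.68%; 95% interval 2.29 to 3.12%) were also listed at moderate overexpression. In the lowest decile, 11 of 6005 peaks (0.183%; 95% interval 0.0915 to 0.328%) were. The moderate peaks that were shared fell on high-overexpression peaks with a median score percentile of 87.0. Higher-scoring peaks were also wider, from a median of 551 bp in the lowest decile to 1258 bp in the highest, which by itself raises the chance of an overlap.

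**Figure D1:**
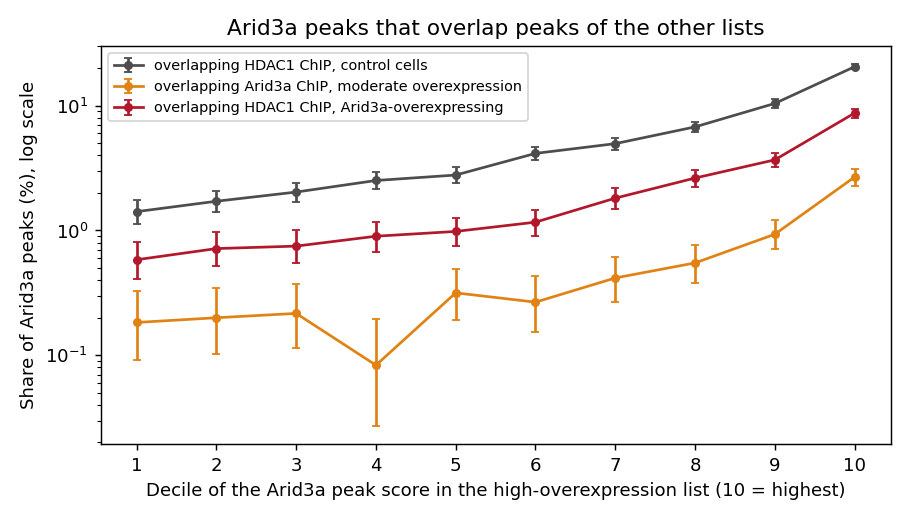
Share of the high-overexpression Arid3a peaks (vertical axis, %, log scale) that overlap a peak of each other list, by decile of the Arid3a score (horizontal axis); points are shares and bars are exact 95% binomial intervals over peaks. The share that overlaps control HDAC1 peaks goes from 1.42% in decile 1 to 20.5% in decile 10, and that for HDAC1 in overexpressing cells from 0.583% to 8.73%.

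The 2 Arid3a lists also differed in the shape of their regions. The median width was 702 bp at high and 281 bp at moderate overexpression. At moderate overexpression, 449 of 1013 peaks (44.3%; 95% interval 41.2 to 47.4%) were narrower than 250 bp, against 39 of 60047 (0.0649%) at high overexpression. A score of exactly 3100 was carried by 513 moderate peaks, of which 432 were narrower than 250 bp. The narrow moderate peaks overlapped the high-overexpression list in 46 of 449 cases (10.2%; 95% interval 7.60 to 13.4%). The wider ones did so in 306 of 564 cases (54.3%; 95% interval 50.0 to 58.4%). Without the narrow peaks the moderate list therefore held 564 regions, and a majority of them were shared.

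**Figure D2:**
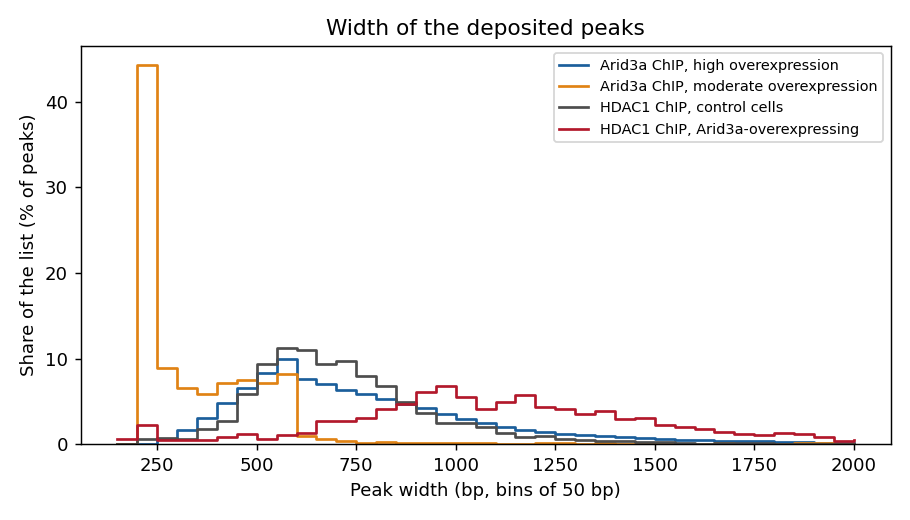
Width of the peaks in each list (horizontal axis, bp, bins of 50 bp, the widest peaks not drawn) against the share of that list's peaks (vertical axis, %). The list from moderate Arid3a overexpression has 44.3% of its peaks under 250 bp, and the HDAC1 list from overexpressing cells is centred on wider peaks (median 1108 bp) than the control list (median 680 bp).

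The highest-scoring Arid3a region at high overexpression was on chromosome 13, from 65727887 to 65729603 (score 3212), and HDAC1 peaks overlapped it in both control and overexpressing cells. The next were on chromosome 3, from 65459983 to 65463800 (score 3192), and on chromosome 12, from 12948079 to 12951144 (score 3186). The chromosome 3 region had no HDAC1 peak, and the chromosome 12 region had an HDAC1 peak in overexpressing cells alone. Regions on chromosome 10 (60877713 to 60882335) and chromosome 1 (183958210 to 183962916) carried HDAC1 peaks in both cell types. Of the 10 highest-scoring regions, 6 overlapped a control HDAC1 peak, 4 overlapped an HDAC1 peak of overexpressing cells, and 0 overlapped a moderate Arid3a peak. A further 24 peaks of this list had a score of exactly 3100, just below these 10. The scale of the score is not known, so the 10 regions are not shown to be the strongest Arid3a sites. At moderate overexpression, the highest score (3222) belonged to a region of 264 bp on chromosome 11, from 106585712 to 106585975, which was listed at high overexpression and overlapped a control HDAC1 peak. The next, on chromosome 1 from 155223685 to 155224202 (score 3218), was listed in the same lists. Of the 10 highest-scoring moderate regions, 6 were listed at high overexpression. In the moderate list 513 peaks had a score of exactly 3100, so the same limit holds there. Those 10 regions do not stand for the high scores of that list. In its lowest decile of score, 50.0% of peaks overlapped a high-overexpression peak. In its highest decile, which includes peaks at 3100, 13.9% did.

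HDAC1 regions were fewer and wider in the list from Arid3a-overexpressing cells than in the list from control cells. The control list was 2.84 times as long and covered 1.78 times as much sequence, while the median width was 1108 bp in overexpressing and 680 bp in control cells. The difference in width was also present in the lowest decile of each list's own score (987 against 571 bp). Whether it came from the libraries or from the peak calling was not tested, and either could alter the numbers of peaks and the overlaps. Of the 3833 control peaks, 644 (16.8%; 95% interval 15.6 to 18.0%) overlapped a peak from overexpressing cells and 3189 did not. Of the 1348 peaks from overexpressing cells, 619 (45.9%; 95% interval 43.2 to 48.6%) overlapped a control peak and 729 did not. Shifting gave at most 0.313% and 1.04%, respectively. When the control list was reduced to its 1348 highest-scoring peaks, 27.1% of them were listed again, and 27.0% of the peaks from overexpressing cells overlapped them.

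Control HDAC1 regions with a high score were listed again more often. In the highest decile of control score, 158 of 383 peaks (41.3%; 95% interval 36.3 to 46.4%) were listed in overexpressing cells, against 39 of 384 (10.2%; 95% interval 7.32 to 13.6%) in the lowest. Conversely, 86 of 134 peaks (64.2%; 95% interval 55.4 to 72.3%) in the highest decile of the overexpressing list were in the control list, against 48 of 135 (35.6%; 95% interval 27.5 to 44.2%) in the lowest. Peaks in the highest decile were also wider than in the lowest, with medians of 961 and 571 bp in control and 1360 and 987 bp in overexpressing cells. Width by itself raises the chance of an overlap. Chromosome 1 held 12.1% of the control peaks (95% interval 11.1 to 13.2%) and 15.2% of those from overexpressing cells (95% interval 13.3 to 17.2%), but 8.07% of the high-overexpression Arid3a peaks. Among control peaks, chromosome 1 held 114 of the 644 listed again (17.7%; 95% interval 14.8 to 20.9%) and 350 of the 3189 others (95% interval 9.91 to 12.1%). The share of control peaks listed again without chromosome 1 was 15.7%.

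**Figure D3:**
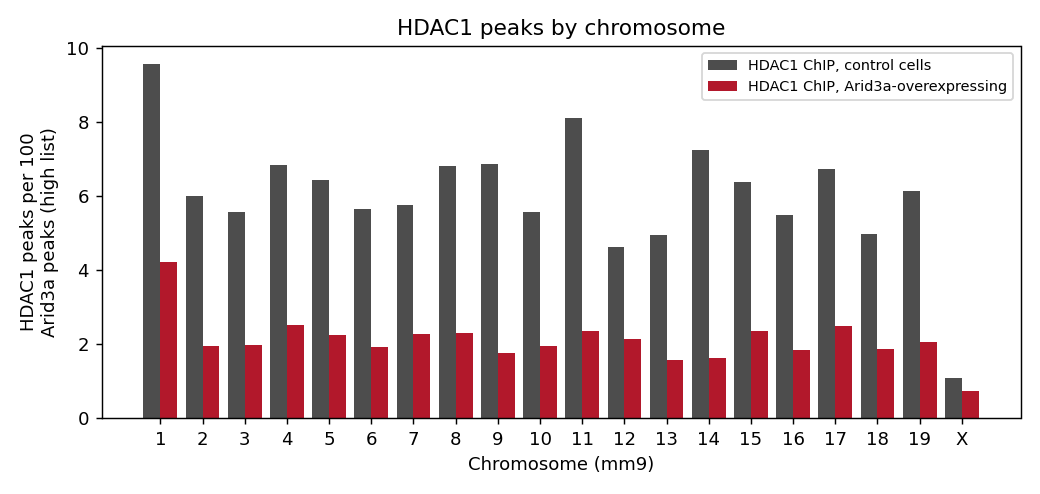
HDAC1 peaks in control and in Arid3a-overexpressing cells, per 100 high-overexpression Arid3a peaks of the same chromosome (vertical axis), by chromosome (horizontal axis). Chromosome 1 has the highest bar in both cell types (9.58 and 4.23), and chromosome X the lowest (1.10 and 0.733).

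Several HDAC1 regions were among the highest-scoring in both cell types. The region on chromosome 7, from 6362596 to 6363198, had a control score of 330.3, the second highest of that list, and the matching region had the highest score of the list from overexpressing cells (307.8, on the scale of that list). Regions on chromosome 15 (76352439 to 76353229) and on chromosome 4 (139814770 to 139815294, and 152173254 to 152174156) were also in the top 10 of both lists. Each of these 4 regions overlapped a high-overexpression Arid3a peak. Of the 10 highest-scoring control regions, 7 were listed again and 8 overlapped a high-overexpression Arid3a peak. The highest-scoring control region, on chromosome 10 from 6764743 to 6764990 (score 373.2), was 248 bp wide, was not listed again and overlapped no Arid3a peak. Of the 10 highest-scoring regions in overexpressing cells, 9 were in the control list and 5 overlapped a high-overexpression Arid3a peak. Of these 10 regions, 3 were narrower than 250 bp, and none of those 3 was on Arid3a. The region outside the control list was 196 bp wide, on chromosome 3, from 104004369 to 104004564.

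Most HDAC1 regions of both cell types coincided with a region of the full high-overexpression Arid3a list, and the share depended on the length of that list. In control cells, 3370 of 3833 HDAC1 peaks (87.9%; 95% interval 86.8 to 88.9%) overlapped such an Arid3a peak. In overexpressing cells, 1192 of 1348 (88.4%; 95% interval 86.6 to 90.1%) did. Shifting gave 3.74% and 4.60% on average, with maxima of 5.17% and 6.90%. The shifts move peaks to any position of the covered span, and no list of another protein was compared. The excess over them therefore does not by itself show that HDAC1 and Arid3a bind together. Arid3a was profiled in overexpressing cells alone, so for control HDAC1 the overlap is between lists from different cells. With the Arid3a list reduced to as many of its highest-scoring peaks as each HDAC1 list holds, 25.4% of the control peaks (95% interval 24.1 to 26.8%) and 18.5% of those from overexpressing cells (95% interval 16.5 to 20.7%) were on Arid3a. The reduced Arid3a list was shorter for the overexpressing cells, so these shares are not comparable with each other. By midpoints within 250 bp, 58.5% of the peaks from overexpressing cells were. Fewer HDAC1 peaks coincided with the much shorter moderate Arid3a list: 57 of 3833 (1.49%; 95% interval 1.13 to 1.92%) in control cells and 26 of 1348 (1.93%; 95% interval 1.26 to 2.81%) in overexpressing cells, against 0.0484% and 0.0665% on average by shifting. Seen from Arid3a, 5.73% of the high-overexpression peaks overlapped a control HDAC1 peak and 2.19% an HDAC1 peak of overexpressing cells. Of the moderate peaks, 5.63% (95% interval 4.29 to 7.23%) and 2.57% (95% interval 1.68 to 3.74%) did. The high-overexpression shares depended on the Arid3a score, as the plot by decile shows. The number of Arid3a peaks with HDAC1 in overexpressing cells, divided by the number with HDAC1 in control cells, ranged from 0.281 to 0.425 over the deciles and was 0.383 over all. The ratio of list lengths, 0.352, counts HDAC1 peaks and is not a matching reference, since 1 HDAC1 peak can overlap several Arid3a peaks. In overexpressing cells 1192 HDAC1 peaks overlapped 1318 Arid3a peaks, and in control cells 3370 overlapped 3439.

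The coincidence with Arid3a was high for HDAC1 regions listed in both cell types and for those listed in either alone. Of the 644 control peaks that were listed again, 587 (91.1%; 95% interval 88.7 to 93.2%) overlapped a high-overexpression Arid3a peak. Of the 3189 that were not, 2783 (87.3%; 95% interval 86.1 to 88.4%) did. Of the 729 peaks listed in overexpressing cells alone, 626 (85.9%; 95% interval 83.1 to 88.3%) did, and 56.3% did by midpoints within 250 bp. With the Arid3a list reduced to its 3833 highest-scoring peaks, 37.7% (95% interval 34.0 to 41.6%) of the control peaks listed again and 23.0% (95% interval 21.5 to 24.5%) of those not listed again were on Arid3a. With the Arid3a list reduced to 1348 peaks, 14.4% of the peaks listed in overexpressing cells alone were, a value that is not comparable with the other 2 because the Arid3a list is shorter.

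Seen the other way, control HDAC1 regions on an Arid3a region were listed again in 587 of 3370 cases (17.4%; 95% interval 16.2 to 18.7%), and those off Arid3a regions in 57 of 463 cases (12.3%; 95% interval 9.46 to 15.7%). The odds ratio over deciles of the control HDAC1 score was 1.56 (95% interval 1.16 to 2.10). With peak width added as a stratum it was 1.36 (95% interval 0.996 to 1.86), and with overlap defined by midpoints within 250 bp it was 1.13 (95% interval 0.923 to 1.39). Among the control regions on Arid3a, split into 4 equal groups by Arid3a score, those in the group of highest scores were listed again in 222 of 843 cases (26.3%; 95% interval 23.4 to 29.4%), and those in the group of lowest scores in 105 of 843 (12.5%; 95% interval 10.3 to 14.9%). The order was the same among control peaks with an HDAC1 score in the lower 50% (18.3% against 7.91%) and in the upper 50% (33.2% against 18.1%).

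**Figure D4:**
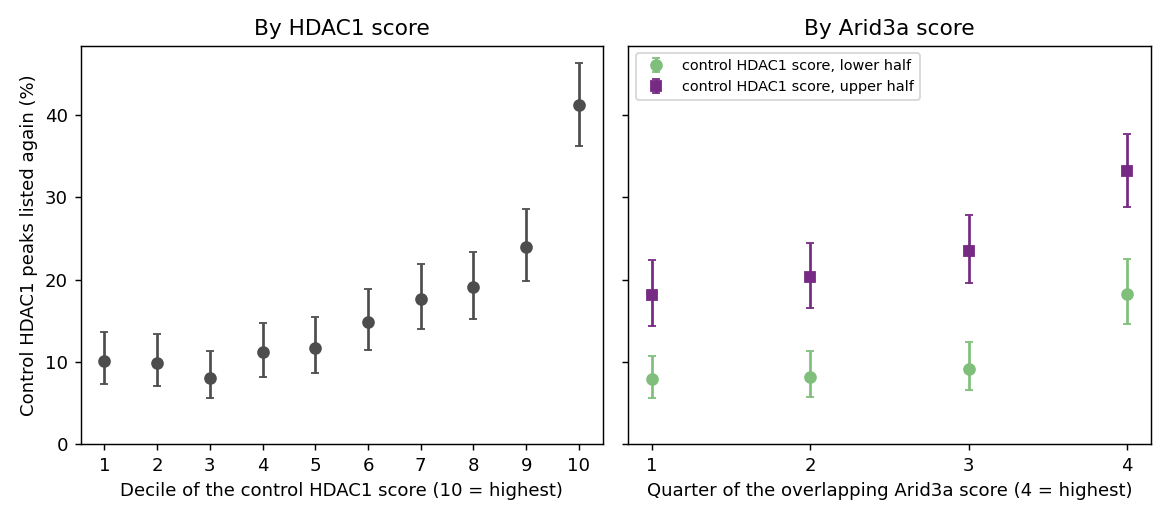
Share of control HDAC1 peaks that were listed again in Arid3a-overexpressing cells (vertical axes, %), by decile of the control HDAC1 score (left) and, for those on a high-overexpression Arid3a peak, by group of the Arid3a score (4 equal groups, 4 the highest) for HDAC1 scores in the lower and the upper 50% (right); bars are exact 95% binomial intervals over peaks. The share goes from 10.2% in HDAC1 decile 1 to 41.3% in decile 10, and at lower and at upper HDAC1 scores it is highest in the group of highest Arid3a scores (18.3% and 33.2%).

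Among HDAC1 regions on Arid3a that were listed in control cells alone, the highest score belonged to a region of 1750 bp on chromosome 17, from 35640719 to 35642468 (score 280.7), which was sixth in the whole control list. It was followed by regions on chromosome 2 from 167013873 to 167015090 (score 208.8), on chromosome 15 from 58912379 to 58914230 (score 195.5) and on chromosome 14 from 100683353 to 100684769 (score 193.2). A region on chromosome 14, from 7721121 to 7722991, was the only one of the 10 that also overlapped a moderate Arid3a peak. Among regions on Arid3a listed in overexpressing cells alone, the highest score belonged to a region on chromosome 4, from 150481599 to 150483228 (score 139.6). Regions on chromosome 19 from 42330206 to 42330915 (score 125.4), on chromosome 11 from 97660439 to 97662174 (score 124.3) and on chromosome 3 from 87945660 to 87947761 (score 118.2) followed. The 10 highest of these scores lay between 106.1 and 139.6, and 0 of the 10 regions overlapped a moderate Arid3a peak.

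A small set of regions was listed in all 4 peak lists. Of the moderate Arid3a peaks, 17 overlapped a peak of each of the other 3 lists. The regions given here were chosen after their values had been seen. They lay on chromosome 1 from 11386118 to 11386387, on chromosome 2 from 168590938 to 168591253, on chromosome 5 from 24104961 to 24105319, on chromosome 8 from 86590239 to 86590795 and on chromosome 18 from 40467669 to 40468098. Of the 17, 4 lay on chromosome 13 between 65592720 and 66817112.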

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

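Leaving out peaks under 250 bp, leaving out chromosome 1, the stratification of the odds ratio by score and its other forms, and the odds ratio between groups of Arid3a score were chosen after the data had been seen. No test between groups was possible with 1 library each, so the alternatives are compared by whether a share left the 95% interval of its main value. The values are given in the order moderate Arid3a peaks in the high list, control HDAC1 peaks listed again, HDAC1 peaks of overexpressing cells in the control list, and then the shares on high-overexpression Arid3a peaks of control HDAC1, HDAC1 of overexpressing cells, control HDAC1 listed again, control HDAC1 not listed again, and HDAC1 in overexpressing cells alone. With midpoints within 250 bp the 8 shares were 22.7%, 12.7%, 36.1%, 62.4%, 58.5%, 63.8%, 62.1% and 56.3%. With the top 50% of each list they were 12.8%, 14.6%, 40.7%, 75.6%, 78.9%, 80.4%, 74.8% and 77.2%. The first of these is no stricter threshold for the moderate Arid3a list, where 527 of 1013 peaks have a score of 3100 or more and the limit falls among tied, mostly narrow peaks. With equal list sizes they were 7.11%, 27.1%, 27.0%, 25.4%, 18.5%, 37.7%, 23.0% and 14.4%. The 18.5% and 14.4% rest on a shorter Arid3a list than the shares of control HDAC1 on Arid3a. With overlap of at least 50% of the shorter peak, the share on Arid3a was 85.2% for control HDAC1, 88.2% for those listed again and 84.6% for those not listed again, and the other 5 shares stayed within their intervals. With peaks widened by 500 bp, 42.1% of the moderate Arid3a peaks were in the high list, and 90.5% of control HDAC1 peaks and 90.01% of those not listed again were on Arid3a. Without peaks under 250 bp, the moderate list held 564 peaks, of which 54.3% were in the high list, and the shares on Arid3a were 91.1% for HDAC1 of overexpressing cells and 89.8% for HDAC1 in overexpressing cells alone. Removal of X, Y and unplaced contigs moved 0 of 11 shares out of their intervals, removal of chromosome 1 moved 0 of 11, and removal of the 20 joined regions with a peak of all 4 lists moved 2 of 11, both of them HDAC1 shares on moderate Arid3a peaks. Each removed region holds HDAC1 and moderate Arid3a peaks by definition, so their removal lowers these shares by construction. The odds ratio of being listed again was above 1 in each of its 6 other forms, and its interval included 1 with width strata (1.36) and with midpoints within 250 bp (1.13). Between the highest and lowest groups of Arid3a score it was 2.40 stratified by HDAC1 score and 2.27 with width added. No paired analysis was possible because each group holds 1 library and no result comes from a test. Other promoter windows, TSS windows, matched random gene lists and sequence widths were not run, since these comparisons need an annotation or a genome of the build of the peaks. The causes of these shifts were not tested. Depth is unknown for every library, so it cannot be said which absent peaks were below detection.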

Other observations

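The tests of the narrow Arid3a peaks, of dense blocks on chromosome 1 and of the shorter HDAC1 list were chosen after the results had been seen, and so were the blocks and regions described here. The tests of the chromosome 1 share at matched Arid3a score and of the rank of chromosome 1 were chosen after the excess on that chromosome had been seen, but before their own outcomes were known.

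Peaks gathered in blocks that the comparisons above did not describe. On chromosome 13, the block from 65.5 to 67.0 Mb held 124 high-overexpression and 5 moderate Arid3a peaks, 14 control HDAC1 peaks and 10 HDAC1 peaks from overexpressing cells. On chromosome 6, a block from 47.6 to 47.71 Mb held 14 high-overexpression Arid3a peaks with a median width of 2200 bp, 5 moderate Arid3a peaks, and the 3 widest control HDAC1 peaks, between 2254 and 3432 bp. The densest windows of 1 Mb in the high-overexpression Arid3a list were 52 to 53 Mb of chromosome 7, with 137 peaks, and 97 to 98 Mb of chromosome 11, with 136, against a median of 16 over windows with any peak. The densest window of the moderate list, 3 to 4 Mb of chromosome 9, held 21 peaks. Of these, 19 lay between 3000000 and 3038355, and the first 3.1 Mb of chromosome 9 held 0 peaks in the high-overexpression list and in both HDAC1 lists. A region on chromosome 17 was 5963 bp wide at high overexpression (39979940 to 39985902) and 5937 bp wide at moderate overexpression (39979942 to 39985878), and both peaks had a score of 3100. Repeated sequence and the uniqueness of read alignment were not examined, so it was not tested whether these blocks and regions reflect binding.

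The moderate Arid3a list held many narrow peaks with a score of exactly 3100. If these were the strongest Arid3a sites seen again at a lower level of protein, they would be shared at least as often as wider peaks, but peaks under 250 bp were shared in 10.2% of cases and wider ones in 54.3% (95% interval 50.0 to 58.4%). Random positions of all the narrow peaks are argued against as well, since the highest of 1000 shifts gave 4.68%. However, 403 of the 449 narrow peaks overlapped no high-overexpression peak, so random positions of most of them are not excluded. Stacks of duplicated reads may produce such peaks, which stays open because the lists hold no reads. Binding particular to the moderate clone also stays open and was not tested.

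Chromosome 1 held an excess of HDAC1 peaks in both cell types (9.58 and 4.23 per 100 high-overexpression Arid3a peaks, against 6.21 and 2.10 on the other autosomes) and also of moderate Arid3a peaks (11.6% of that list, 95% interval 9.74 to 13.8%; 2.44 against 1.62), with rank 1 of 19 in all 3 lists, so that the excess is not particular to HDAC1. Arid3a regions of the same score deciles would place 9.27% of the control HDAC1 peaks on Arid3a there, below the observed 12.9% (95% interval 11.8 to 14.1%). This argues against a larger share of sites in the high deciles as the whole cause. The highest decile spans scores from 375.9 to 3212, however, so a larger share of the strongest sites within it is not excluded. Of 20 bins of 10 Mb, 16 had more control HDAC1 peaks per Arid3a peak than the other autosomes together, which argues against a few dense blocks. A candidate explanation is more copies of chromosome 1 in all of the cells, for which chromosome 1 should rank first of the 19 autosomes by median Arid3a score at high overexpression, and it did (rank 1, 116.2), while chromosome X, present once in male cells, was the lowest of 20 (94.3). Whether the score follows the number of copies is not known, however, and among the next autosomes its rank did not go with the HDAC1 ratio. Chromosomes 13, 14 and 12, which ranked 2, 3 and 4 (111.5, 108.9 and 108.6), had 4.95, 7.25 and 4.62 control HDAC1 peaks per 100 Arid3a peaks, on both sides of the 6.21 of the other autosomes. Chromosome 11, which ranked 5 (105.9), had 8.10, above that value. It held 9.26% of the control HDAC1 peaks (95% interval 8.36 to 10.2%) and 7.30% of the high-overexpression Arid3a peaks. Chromosome X, the lowest by score, had 1.10. Copy number was not measured, and binding particular to chromosome 1 remains an untested hypothesis.

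The HDAC1 list was shorter in overexpressing cells. A less sensitive library predicts that control peaks of high score are listed again more often, which held (10.2% in the lowest decile, 41.3% in the highest), and, as the whole cause, that nearly all of the strongest peaks of the shorter list lie near a control peak. Of its highest decile 68.6% (95% interval 59.5 to 76.7%) did (peaks under 250 bp left out, peaks widened by 500 bp), but the share that equally sensitive libraries would reach is unknown, so lower sensitivity cannot be told apart from a loss of HDAC1 that is even over all sites, which predicts the same. Control peaks of high score were also wider, which by itself raises the chance that they are listed again. Preferential loss of HDAC1 at Arid3a sites predicts an odds ratio of being listed again below its value with no change, which may itself differ from 1. High-scoring Arid3a peaks overlapped HDAC1 peaks more often, but the share of HDAC1 peaks on Arid3a did not rise with the HDAC1 score. It was 87.2% in the lowest and 86.9% in the highest decile in control cells, and 87.4% and 82.1% in overexpressing cells. Stratified by score, the odds ratio on against off Arid3a was 1.56 (95% interval 1.16 to 2.10), beside 1.83 (1.27 to 2.62) in the other direction. By midpoints it was 1.13 (0.923 to 1.39). With width added it was 1.36 (0.996 to 1.86) beside 1.80 (1.21 to 2.67). Between the highest and lowest Arid3a score groups it was 2.40 (1.84 to 3.13) beside 1.55 (1.11 to 2.16) by score. With width added that became 2.27 (1.74 to 2.96) beside 1.65 (1.17 to 2.34). The intervals of each pair overlap. The other direction also counts the same shared regions and would itself change with a loss, so the value with no change is unknown. Preferential loss therefore cannot be told apart from no preference. A different background library or peak calling behind each list was not tested either, although the peaks of the shorter list were wider.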
